A study of Mus musculus with 6 samples.

How the data were processed

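B16-F3, a mouse melanoma cell line, was sorted by flow cytometry into high-pigmented cells (HPC) and low-pigmented cells (LPC), and 3 RNA libraries were made from each population. Per the labels' protocols, the libraries were prepared from total RNA with the QuantSeq 3' mRNA-Seq FWD kit, which reads the 3' end of polyadenylated transcripts, and were sequenced on a NextSeq 500. Per the submitters' processing notes, STAR was the aligner named and GRCm38 the genome build. The counting program, the annotation release, the use of strand and the use of molecular identifiers are not given in the sources used here.

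The authors deposited 1 table of raw counts per gene, not normalized, with 1 column for each of the 6 libraries. It holds 22740 genes, and the columns were matched to samples by their names. Each count is a whole number of reads assigned to a gene. Since reads lie at transcript ends, counts do not scale with transcript length as they do in whole-transcript libraries, and a gene whose 3' end is shared with or misplaced in the annotation can be miscounted. Unless molecular identifiers were used, reads copied by PCR are not independent molecules. The labels do not say whether the replicates came from separate cultures or sorts, so p-values measure only the spread between these libraries, which may be technical.

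Genes were filtered with edgeR's filterByExpr, which left 11921 genes, and libraries were scaled with TMM factors, which correct for composition. The test was edgeR's quasi-likelihood F-test (edgeR 4.0.16 in R 4.3.3) with group as the only term and 4 residual degrees of freedom. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called changed, and log2 fold changes are HPC over LPC. CPM values, counts scaled to a common library size, were computed from the deposited counts with TMM factors and are given as mean ± SD over 3 libraries. Standard errors (SE) of log2 fold changes were derived from the quasi-likelihood F statistic.

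The groups share replicate numbers, and a fit with the replicate number as a block was planned beside the one without it. The numbers were checked by correlating deviations from the group means across genes. The correlation was 0.42 for the libraries numbered 1, 0.35 for those numbered 2 and 0.65 for those numbered 3, and all 6 libraries correlated best with the library of their own number in the other group. All 3 exceeded the minimum of 0.1 set for pairing, so the pairing comes from the data and not from the labels. Deviations of 3 libraries from their own mean cancel out, so some matching tends to correlate even without true pairs. The check is therefore weak evidence of pairs. Blocked values are given where they change a call. The blocked fit has 2 residual degrees of freedom.

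In total, 25 gene lists were fixed before the data were examined. They cover pigment production, melanosome biogenesis and transport, melanocyte lineage regulators, the dedifferentiated melanoma state, YAP/TAZ and TGF-beta response, extracellular matrix, DNA replication, mitosis, p53 targets, lysosome, oxidative phosphorylation, mitochondrially encoded transcripts, hypoxia and glycolysis, ATF4 response, unfolded protein response, interferon response, MHC class I presentation, immediate early and heat shock genes, antioxidant genes, cholesterol synthesis, ribosomal proteins, ribosome biogenesis with MYC targets, histones, and markers of immune cells and of fibroblasts, endothelium and keratinocytes. They were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over all 25 lists. The same test with an estimated correlation, and fry, a rotation test of whether a list moves on balance one way, were run beside it.

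Genes are named by a rule fixed before the data were examined. It takes 10 core genes, the 8 largest changes in each direction among called genes with a mean CPM of at least 5, non-overlapping groups and an established symbol, and up to 3 called members of each list. Because few genes passed without the block, the rule was applied to the blocked fit as well, a choice made after the values were seen. Coordinates are those of GENCODE M21 on GRCm38, in which 21118 of the 22740 gene identifiers (92.9%) were found, all on the chromosome that the table gives.

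The tests were run first on simulated counts drawn from these libraries' means and dispersions. Over 11845 simulated genes of the HPC against LPC comparison without the block, 71.7% of the genes changed 2-fold and 98% of those changed 4-fold were recovered, with 7 false calls among 176. With the block, over 11868 simulated genes, 91.9% and 100% were recovered, with 13 false calls among 204. Of 200 random lists, 2.5% had a camera p under 0.05. The counts were simulated without correlation between genes, so this does not check camera p-values for lists of co-regulated genes.

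Alternatives were other scalings (RLE, upper quartile, library size only), DESeq2 1.42.0, limma-voom, no filter, a filter of at least 5 CPM in at least 3 libraries, the block, and leaving out each library. Alternatives to the blocked fit, among them a correction for transcript length and for the GC content of the last 500 nucleotides, were added after seeing the data. This correction fitted splines with 4 degrees of freedom in each library, and 98.1% of the tested genes had values for it. No library was left out as a duplicate, since chi-square per degree of freedom between libraries of one group ran from 28.9 to 54.7.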

Results

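B16-F3 is a melanoma line from the mouse, and melanin inside its cells changes how they scatter light, which allows cells with much and with little pigment to be sorted apart. The libraries of HPC and LPC, 3 of each, measure mRNA levels by counting reads at transcript 3' ends, and the design asks which genes differ between the more and the less pigmented cells of one line. Total counts per library were 18131623, 22186743 and 19721577 in HPC replicates 1, 2 and 3, and 14695822, 18810435 and 14881833 in LPC replicates 1, 2 and 3. Between 13715 and 14141 genes had at least 1 count in a library. The 10 most abundant genes took 6.39% to 7.73% of the counts, and mitochondrial genes 2.07% to 3.21%.

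Zscan10, a zinc finger gene of embryonic stem cells, had the largest difference among genes that passed the test without the block. Its level was 17.9 ± 5.70 CPM in HPC and 171 ± 47.7 CPM in LPC (SD, n = 3 each), 9.57-fold lower in HPC (edgeR quasi-likelihood test, log2 fold change -3.26, SE 0.29, adjusted p = 0.029). Kmt2a, which encodes a histone H3 lysine methyltransferase, stood at 243 ± 48.0 CPM in HPC and 718 ± 108 CPM in LPC, 2.96-fold lower in HPC (log2 fold change -1.56, SE 0.18, edgeR adjusted p = 0.046). The transcription factor Nfix was 2.78-fold lower in HPC, at 10.3 ± 1.28 against 28.7 ± 3.56 CPM. Myc, the growth-promoting transcription factor, was 2.25-fold lower, at 33.1 ± 4.06 against 74.6 ± 7.41 CPM. For all 4 genes the difference had the same sign in each of the 3 pairs of equally numbered libraries. The naming rule's demand for non-overlapping groups fixed this in advance. Over all tested genes, 14.3% had non-overlapping groups, against 10% by chance.

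Zscan10 (ENSMUSG00000023902) lies on chromosome 17 from 23600856 to 23611019 on the plus strand, Kmt2a (ENSMUSG00000002028) on chromosome 9 from 44803355 to 44881296 on the minus strand, Nfix (ENSMUSG00000001911) on chromosome 8 from 84699876 to 84800344 on the minus strand, and Myc (ENSMUSG00000022346) on chromosome 15 from 61985391 to 61990374 on the plus strand, all in GRCm38. Kmt2a overlaps Gm48314 on its own strand, and Nfix overlaps Lyl1 and G430095P16Rik on the opposite strand. Their counts are uncertain to the extent that reads of these neighbours were counted with them.

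In total, 5 of 11921 genes passed (edgeR, adjusted p under 0.05), all lower in HPC and all by at least 2-fold. The fifth, Shisa2, was named after its values were seen because its mean of 4.90 CPM lies under the limit for named genes, and was 4.97-fold lower in HPC, at 1.64 ± 0.18 against 8.16 ± 1.32 CPM. None passed in the direction of HPC, where the smallest adjusted p was 0.071, while at an unadjusted p under 0.05 there were 603 genes higher and 514 lower in HPC. DESeq2 called 122 genes higher and 102 lower, and limma-voom called 5 in all. With the replicate number as a block, edgeR called 301 genes, 170 higher and 131 lower in HPC, of which 129 differed at least 2-fold. All 5 genes were among them. Without the block the count fell to 0 when HPC replicate 1, 2 or 3 or LPC replicate 2 was left out, and was 17 without LPC replicate 1 and 43 without LPC replicate 3. With the block it was 2947 without the pair numbered 1, 0 without the pair numbered 2 and 196 without the pair numbered 3. Each of these fits left 1 residual degree of freedom, so their p-values and counts carry little weight. Without the pair numbered 2, the genes named here from the blocked fit had edgeR adjusted p from 0.066 for Tyr to 0.46 for Itgav. Without the block, Ptprf, H1fx, Sall4, Cxcl10 and Tap2 passed when LPC replicate 1 was left out (edgeR adjusted p from 0.038 for Ptprf to 0.043 for H1fx). Trpm1, Met, Tbc1d2, H1fx, Zfp521, Vldlr and Egr1 passed when LPC replicate 3 was left out (edgeR adjusted p from 0.035 for Trpm1 to 0.048 for Egr1).

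Tyr, which encodes tyrosinase, the rate-limiting enzyme of melanin synthesis, was at 919 ± 70.3 CPM in HPC and 187 ± 109 CPM in LPC (SD, n = 3 each). Without the block it did not pass with edgeR (log2 fold change 2.30, SE 0.45, adjusted p = 0.17) but did with DESeq2 (adjusted p = 0.0092), and with the block it did (log2 fold change 2.52, SE 0.35, edgeR adjusted p = 0.021). Over the alternatives to the unblocked fit, the block among them, the adjusted p of Tyr ran from 0.0092 to 0.41. Over the alternatives to the blocked fit it ran from 8.2e-171 without the pair numbered 1, which left 1 residual degree of freedom, to 0.066 without the pair numbered 2, where the log2 fold change of Tyr was 1.93. The LPC libraries spread widely, at 261, 62.2 and 238 CPM for replicates 1, 2 and 3, and all lay below the lowest HPC library, at 855 CPM. Tyr (ENSMUSG00000004651) lies on chromosome 7 from 87424771 to 87493512 on the minus strand, with no overlapping gene.

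Trpm1, a cation channel gene of melanocytes, was at 345 ± 113 CPM in HPC and 80.2 ± 55.6 CPM in LPC, and was 4.87-fold higher in HPC with the block (edgeR adjusted p = 0.0077, against 0.21 without it). The receptor tyrosine kinase gene Met was at 1572 ± 244 and 391 ± 197 CPM, 4.42-fold higher with the block (edgeR adjusted p = 0.019, against 0.16 without it). Cited1, a transcriptional coactivator, was at 61.5, 136 and 326 CPM in HPC replicates 1, 2 and 3 and at 23.5, 71.7 and 205 CPM in LPC replicates 1, 2 and 3. It was 1.97-fold higher in HPC with the block (edgeR adjusted p = 0.022), whereas without it the groups overlapped, the edgeR adjusted p was 0.82 and the sign reversed without HPC replicate 3 (log2 fold change -0.013).

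The most abundant pigment cell transcripts did not pass with or without the block. Dct, the dopachrome tautomerase gene, was at 13149 ± 931 CPM in HPC and 13787 ± 626 CPM in LPC, and Tyrp1, encoding tyrosinase-related protein, at 8431 ± 591 and 7351 ± 475 CPM. Pmel, the melanosome fibril gene, was at 9892 ± 930 and 9214 ± 1246 CPM, and Mlana at 1265 ± 291 and 1339 ± 51.7 CPM. The lineage transcription factors Mitf, at 547 ± 62.9 and 529 ± 76.9 CPM, and Sox10, at 733 ± 70.1 and 763 ± 35.5 CPM, did not pass either. The log2 fold changes of these 6 genes were -0.07 for Dct, 0.20 for Tyrp1, 0.10 for Pmel, -0.08 for Mlana, 0.05 for Mitf and -0.06 for Sox10, with SEs of 0.12, 0.12, 0.14, 0.17, 0.14 and 0.12. The sign reversed for Mlana without HPC replicate 3 (0.047), for Mitf without HPC replicate 1 (-0.040) or LPC replicate 2 (-0.034) and for Sox10 without HPC replicate 2 (0.020). With the block, Mlana passed as lower in HPC without the pair numbered 1 (log2 fold change -0.30, edgeR adjusted p = 0.0077) and stood at 0.054 without the pair numbered 3. Both fits left only 1 residual degree of freedom, so this pass carries little weight.

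**Figure D1:**
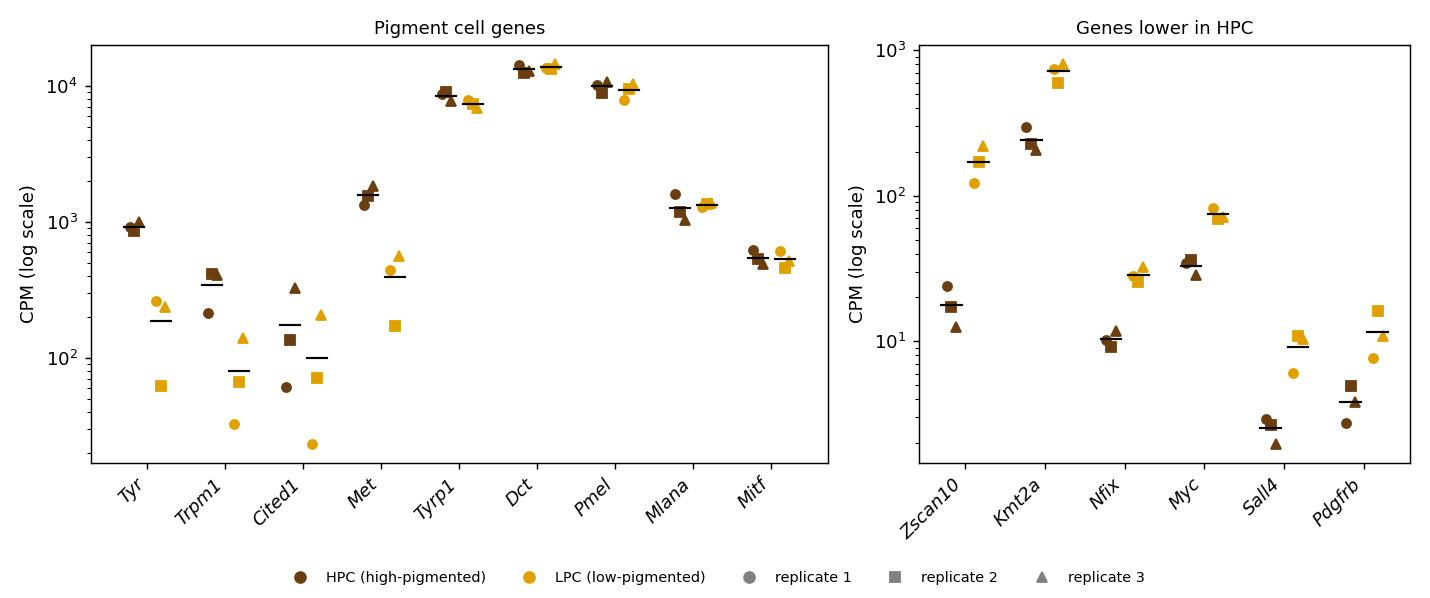
CPM (log scale) of 9 pigment cell genes and 6 genes lower in HPC in each library; colour gives the group, symbol the replicate number and the black line the mean of 3 libraries. Tyr, Trpm1 and Met lay higher in all 3 HPC libraries than in any LPC library, which the naming rule required of largest changes such as Met. Tyrp1, Dct, Pmel, Mlana and Mitf lay at similar levels. With edgeR and the filterByExpr filter on all 6 libraries, Zscan10, Kmt2a, Nfix and Myc passed without the block. Sall4 and Pdgfrb passed there only with it (DESeq2 called both without it).

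The pigment production list had 16 tested members, of which 13 had positive log2 fold changes, with a median of 0.36 (camera, higher in HPC, adjusted p = 0.00011). The adjusted p was 0.67 with an estimated correlation. Without the block edgeR called no member over all genes (5 at an unadjusted p under 0.05, all higher) and 2 adjusted over the list alone, while DESeq2 called Tyr and Trpm1 and limma-voom none. With the block in edgeR, 5 members were higher in HPC, namely Tyr, Trpm1, Cited1, Oca2 and Slc24a4, none was lower, and 9 were higher adjusted over the list alone. The list's median difference was 0.57, 0.28 and 0.17 in the pairs numbered 1, 2 and 3. Of 30 tested genes of melanosome biogenesis and transport, 1 changed with the block, Myo5a, which encodes the motor that carries melanosomes (1.55-fold higher, edgeR adjusted p = 0.0495), and the list did not pass (camera adjusted p = 0.47). After the length and GC correction of the blocked fit the log2 fold change of Myo5a was 0.51, against 0.63 before, and it no longer passed (edgeR adjusted p = 0.076). Of 16 lineage regulators, Tfap2a was 1.52-fold lower in HPC with the block (edgeR adjusted p = 0.024), and the list did not pass (camera adjusted p = 0.068). The lineage list passed, lower in HPC, without LPC replicate 2.

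Among the other largest differences with the block, Tinagl1, Gja1, Fam212b, Tbc1d2 and Hmcn2 were higher in HPC by 3.93-, 4.14-, 3.77-, 3.75- and 3.71-fold. Gja1 encodes the gap junction protein connexin 43. Ptprf, a receptor tyrosine phosphatase gene, H1fx, a linker histone gene, Zfp521 and Sall4, zinc finger genes, Adcy5, an adenylyl cyclase gene, Atp2b4, a calcium pump gene, and Pdgfrb, a growth factor receptor gene, were lower by 5.85-, 4.66-, 3.58-, 3.56-, 3.24-, 3.02- and 3.00-fold. The edgeR adjusted p of these 12 genes with the block ran from 0.0077 to 0.029. Without the block, none passed with edgeR on all 6 libraries after the filterByExpr filter. With no filter, edgeR without the block called at least H1fx, as lower in HPC. DESeq2 without the block called all 12 but Fam212b. Fam212b varied widely within HPC, at 19.8 ± 17.9 CPM in HPC and 4.35 ± 1.65 CPM in LPC.

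Of 11 tested genes of the dedifferentiated or neural crest-like melanoma state, Pdgfrb and Ngfr were lower in HPC with the block and none was higher. Ngfr, the nerve growth factor receptor gene that marks neural crest-like cells, was at 0.44 ± 0.60 CPM in HPC and 3.51 ± 2.71 CPM in LPC, 9.13-fold lower with the block (edgeR adjusted p = 0.031, against 0.38 without it). Its counts were 20, 0 and 4 in HPC replicates 1, 2 and 3 and 98, 44 and 24 in LPC replicates 1, 2 and 3. The blocked log2 fold change of Ngfr, -3.19, was -4.26 without the pair numbered 1 and -2.66 without the pair numbered 2. Without the block it was -3.04, and ran from -2.22 without LPC replicate 1 to -5.08 without HPC replicate 1. Axl, a receptor kinase gene of the same list, was at 22.6 ± 10.7 and 25.4 ± 14.8 CPM and did not pass (edgeR adjusted p = 0.96), and the sign of its difference reversed without HPC replicate 1 or LPC replicate 3. The list itself did not pass (camera adjusted p = 0.33).

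The list of p53 targets and cell cycle arrest, here the p53 list, lay higher in HPC. The tumour suppressor p53 halts the cell cycle after DNA damage, and the list also holds other arrest genes such as Cdkn1b and Rb1. Of 20 tested members 18 had positive log2 fold changes, with a median of 0.79 (camera adjusted p = 2.3e-08). The adjusted p was 0.67 with an estimated correlation. With the block edgeR called 6 members higher and none lower, and 15 higher adjusted over the list alone. Without the block edgeR called none over all genes (13 at an unadjusted p under 0.05, all higher) and 7 adjusted over the list alone, DESeq2 called 6, Ccng1 and Phlda3 among them, and limma-voom none. The 6 of the blocked edgeR fit were Ccng1, Phlda3, Zmat3, Cdkn1a, Aen and Tnfrsf10b. Ccng1, the cyclin G gene, was at 376 ± 192 CPM in HPC and 124 ± 28.7 CPM in LPC, 2.83-fold higher with the block (edgeR adjusted p = 0.015). Phlda3, an inhibitor of Akt, was 2.19-fold and Zmat3, a zinc finger gene, 1.78-fold higher. Zmat3 no longer passed after the length and GC correction (log2 fold change 0.74, against 0.83 before, edgeR adjusted p = 0.057). HPC replicate 1 stood highest, with a list median 0.87 above the mean of the 6 libraries on the log2 scale, against 0.0013 and 0.31 in HPC replicates 2 and 3, and the pair differences were 1.06, 0.49 and 0.38. That library also had the highest share of mitochondrial counts, 3.21% against 2.07% to 2.56% in the others. Whether the level of the p53 list and this share are linked was not tested.

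Of 37 tested mitosis genes 36 had positive log2 fold changes, with a median of 0.45 (camera, higher in HPC, adjusted p = 1.0e-10). The adjusted p was 0.71 with an estimated correlation. With edgeR no member passed over all genes without the block (11 at an unadjusted p under 0.05) or with it (26), and 15 were higher with the block adjusted over the list alone. DESeq2 called none without the block and 11 with it, all higher in HPC, and limma-voom none in either. Mki67, the proliferation marker, was at 744 ± 115 CPM in HPC and 603 ± 235 CPM in LPC and did not pass without the block (edgeR adjusted p = 0.80) or with it (log2 fold change 0.37, edgeR adjusted p = 0.35). With the block and without the pair numbered 1, Mki67 passed as higher in HPC (log2 fold change 0.70, edgeR adjusted p = 1.4e-12). That fit left only 1 residual degree of freedom, so this pass carries little weight. Without the block the log2 fold change of Mki67 ran from 0.067 without LPC replicate 3 to 0.64 without LPC replicate 1. The list's pair medians were -0.074, 0.62 and 0.89, so the pair numbered 1 did not share the difference, and LPC replicate 3 stood lowest, 0.77 below the mean of the 6 libraries. The 39 DNA replication genes had a median log2 fold change of 0.084 (camera, higher in HPC, adjusted p = 0.031) and pair medians of -0.36, 0.33 and 0.54. Their adjusted p was 0.90 with an estimated correlation, edgeR, DESeq2 and limma-voom called no member with or without the block (edgeR, 0 at an unadjusted p under 0.05 without it and 1 with it), and the call ended with no filter (camera adjusted p = 0.052) and without HPC replicate 2. Without LPC replicate 3 it turned to lower in HPC (camera adjusted p = 0.072).

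**Figure D2:**
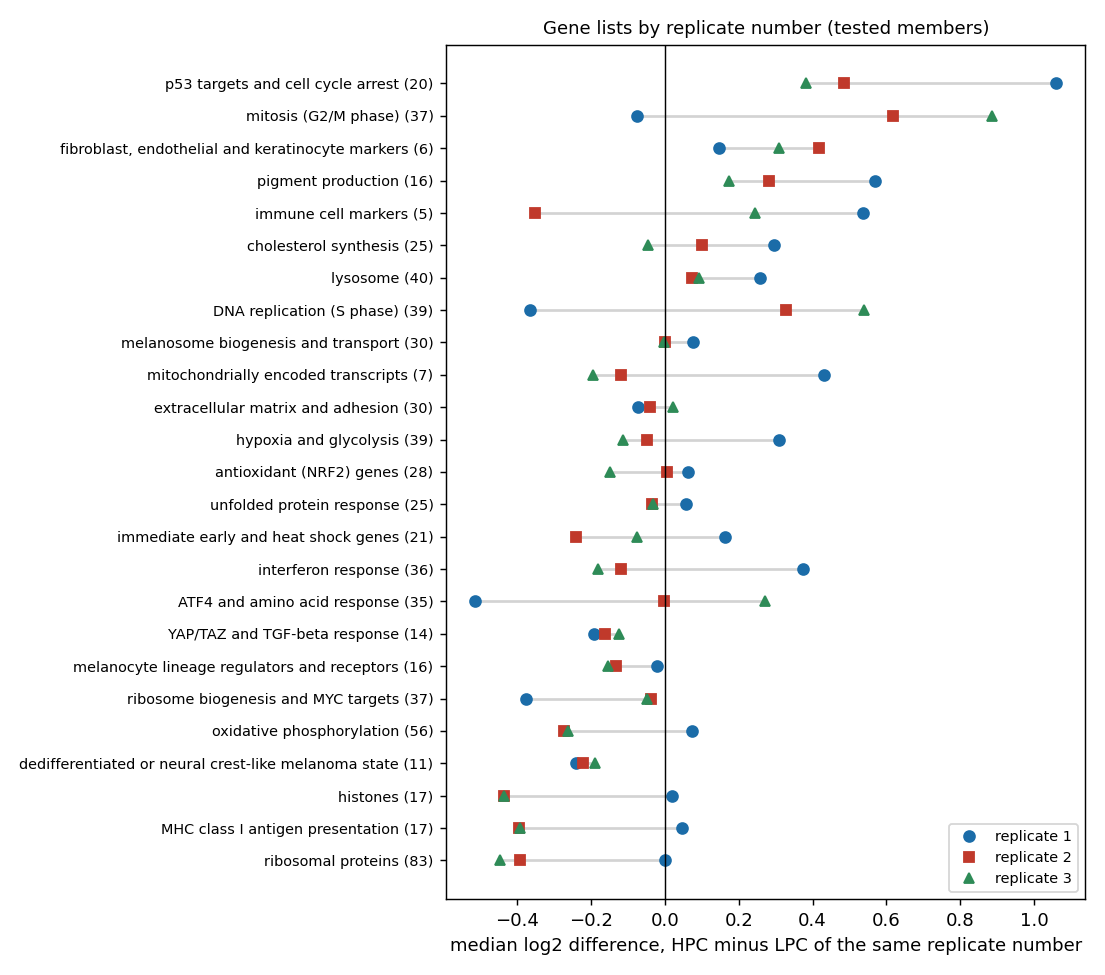
Median log2 difference between HPC and LPC libraries of the same replicate number over the tested members of 25 gene lists; the number of tested members is in parentheses and the symbols are the 3 replicate numbers. The p53 and pigment production lists lay above 0 in all 3 pairs, whereas the mitosis, DNA replication and ribosomal protein lists differed between the pair numbered 1 and the others.

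Of 83 tested ribosomal protein genes 81 had negative log2 fold changes, with a median of -0.27 (camera, lower in HPC, adjusted p = 8.7e-15). The adjusted p was 0.71 with an estimated correlation, and edgeR called no single member without the block (14 at an unadjusted p under 0.05), with it (31) or adjusted over the list alone. DESeq2 with the block called Rpl14 and Rpl22 as lower, and DESeq2 without it and limma-voom called none. The pair medians were -4.2e-05, -0.39 and -0.45. Many ribosomal protein genes have near-identical processed copies in the genome, so their single counts are uncertain. LPC replicate 2, whose trend with transcript length and GC content took 13.8% of its variance against 1.74% to 5.92% in the other libraries, stood highest for the ribosomal protein list (0.32 above the mean of the 6 libraries). The list's median log2 fold change with the block was -0.28 before and -0.19 after that trend was removed from each library. Genes of ribosome biogenesis and MYC targets had a median of -0.15 over 37 members (camera, lower in HPC, adjusted p = 0.011; 0.90 with an estimated correlation), and Myc was the only member that edgeR called over all genes, with or without the block. DESeq2 with the block also called Npm1 and Eif5a as lower. That list's pair medians were -0.38, -0.039 and -0.049. Its call ended without HPC replicate 3 or LPC replicate 2, and without LPC replicate 1 it ended and its direction turned to higher in HPC (camera adjusted p = 0.98).

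Nuclear genes of oxidative phosphorylation had negative log2 fold changes in 54 of 56 members, with a median of -0.15 (camera, lower in HPC, adjusted p = 7.1e-05; 0.88 with an estimated correlation). The pair medians were 0.072, -0.27 and -0.26, so the pair numbered 1 did not share the difference. DESeq2, edgeR and limma-voom called no member with or without the block (edgeR, 0 at an unadjusted p under 0.05 without it and 3 with it), and the list's call ended without HPC replicate 3 or LPC replicate 2. LPC replicate 2 also stood highest for the oxidative phosphorylation list (0.25). Its median with the block was -0.15 before and -0.054 after the length and GC correction (camera adjusted p = 0.037 after it). Lysosome genes had positive values in 31 of 40 members, with a median of 0.14 (camera, higher in HPC, adjusted p = 0.00098; 0.71 with an estimated correlation). Its pair medians were 0.26, 0.074 and 0.093. Neither edgeR nor limma-voom called a member (edgeR, 5 at an unadjusted p under 0.05 without the block and 12 with it), DESeq2 called Atp6v1a as higher in both fits, and the list's call ended without LPC replicate 1.

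Of 17 tested genes of MHC class I antigen presentation 15 had negative log2 fold changes, with a median of -0.23 (camera, lower in HPC, adjusted p = 0.013; 0.71 with an estimated correlation). With the block edgeR called 4 lower and none higher. Without it edgeR called none (4 at an unadjusted p under 0.05), limma-voom none and DESeq2 Tap2 and Psmb8. Tap2, a subunit of the peptide transporter, was at 12.6 ± 2.72 CPM in HPC and 35.4 ± 18.5 CPM in LPC, 2.59-fold lower with the block (edgeR adjusted p = 0.029). H2-K1 was 1.72-fold and H2-Q4 1.69-fold lower, and Psmb8, an immunoproteasome gene, was the fourth. H2-K1 and H2-Q4 are members of a family of similar sequences, so reads may have been divided between them. The list's call ended without HPC replicate 2 or LPC replicate 3, and its pair medians were 0.047, -0.40 and -0.39.

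Of 17 tested histone genes 13 had negative log2 fold changes (median -0.22, camera, lower in HPC, adjusted p = 0.014; 0.71 with an estimated correlation). The pair medians were 0.020, -0.44 and -0.43, so the pair numbered 1 did not share the difference. With the block in edgeR H1fx, H1f0 and H3f3b were lower, by 4.66-, 1.38- and 1.39-fold, and no histone gene was higher. These 3 genes encode linker histones and the replacement histone H3.3, which are made outside S phase. The call ended with no filter (camera adjusted p = 0.69) and without HPC replicate 2 or 3.

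Cholesterol synthesis passed with the block only (median log2 fold change 0.13, camera adjusted p = 0.046, against 0.052 without it; 0.91 with the block and an estimated correlation). The blocked call ended without the pair numbered 1 (camera adjusted p = 0.51) or 2 (camera adjusted p = 0.11). Its pair medians were 0.30, 0.099 and -0.045. Without the block the list passed when HPC replicate 1 or 3 or LPC replicate 2 or 3 was left out. Its only member called by edgeR was Tm7sf2, a sterol reductase gene, 1.73-fold higher with the block. Tm7sf2 overlaps Vps51 on its own strand, so its counts may include reads of that gene.

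The other lists did not pass with camera. Within them, single genes changed in edgeR with the block. Egr1, an immediate early transcription factor gene, was at 4.83 ± 1.31 CPM in HPC and 0.92 ± 0.21 CPM in LPC, 5.24-fold higher with the block (edgeR adjusted p = 0.018, against 0.071 without it), 1 of 21 immediate early and heat shock genes (camera adjusted p = 0.70). Atf6, a sensor of unfolded proteins, was 1.70-fold higher, 1 of 25 genes of that response (camera adjusted p = 0.91). Egr1 and Atf6 were also called as higher without the block by DESeq2 and by edgeR with no filter. Hk2, a hexokinase gene, was 1.47-fold higher, at 222 ± 38.7 against 150 ± 3.70 CPM, and Slc16a3, a lactate transporter gene, was higher at 126 ± 40.3 against 86.0 ± 35.5 CPM, 2 of 39 genes of hypoxia and glycolysis (camera adjusted p = 0.49). Hk2 no longer passed after the length and GC correction (log2 fold change 0.49, against 0.55 before, edgeR adjusted p = 0.071). Hmox1, the heme oxygenase gene, was 1.40-fold higher, 1 of 28 antioxidant genes (camera adjusted p = 0.70). Vldlr, a lipoprotein receptor gene, was 2.30-fold lower, 1 of 35 genes of the ATF4 response (camera adjusted p = 0.33), and Cxcl10, a chemokine gene, was 3.67-fold lower, 1 of 36 interferon response genes (camera adjusted p = 0.70). The interferon list passed as lower in HPC without HPC replicate 3 or LPC replicate 1 and as higher without LPC replicate 3. The ATF4 list passed as lower without HPC replicate 2 or LPC replicate 3, and the hypoxia list as higher without HPC replicate 1 or LPC replicate 3 and as lower without LPC replicate 1.

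Of 30 extracellular matrix and adhesion genes, Col5a1, a collagen gene, and Timp3, a metalloproteinase inhibitor gene, were 1.57- and 1.78-fold lower with the block, and Itgav, an integrin gene, was 1.36-fold higher (camera adjusted p = 0.91). Itgav no longer passed after the length and GC correction (log2 fold change 0.33, against 0.45 before, edgeR adjusted p = 0.078). Ajuba was 1.52-fold lower, 1 of 14 genes of YAP/TAZ and TGF-beta response (camera adjusted p = 0.10), a list that passed as lower without HPC replicate 3 or LPC replicate 2. None of the 7 mitochondrially encoded transcripts tested passed with edgeR, DESeq2 or limma-voom, with or without the block (0 at an unadjusted p under 0.05 in each), nor did the list (camera adjusted p = 0.70). The camera direction differed in sign from the median for the unfolded protein response (median -0.025, mean 0.0098, higher), for the immediate early genes (median -0.037, mean 0.16, higher) and for extracellular matrix (median 0.0080, mean 0.019, lower). Medians of 4 lists changed sign under another scaling, namely extracellular matrix, melanosome biogenesis, mitochondrially encoded transcripts and hypoxia, and no sign is read from them.

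Markers of other cell types were mostly too low to be tested. Of 22 immune cell markers with a count row, 5 were tested, edgeR and limma-voom called none (1 at an unadjusted p under 0.05 in each), DESeq2 called Cd68 with the block, as higher in HPC, and none without it, and the list did not pass (camera adjusted p = 0.41). Of 22 markers of fibroblasts, endothelium and keratinocytes, 6 were tested (camera adjusted p = 0.44). With the block Postn, a matrix gene, was 1.95-fold higher in HPC, at 25.0 ± 7.81 against 12.6 ± 2.72 CPM, and Pdgfra, a growth factor receptor gene, was 2.16-fold lower, at 4.31 ± 1.24 against 9.47 ± 4.03 CPM.

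Of the 25 lists, camera with the preset correlation called 5 higher and 5 lower in HPC, and 6 higher and 5 lower with the block. With an estimated correlation, and with fry, none was called in either fit. The pigment production, mitosis, p53 and ribosomal protein calls held without each library in turn. Arbitrary divisions of the 6 libraries also gave up to 12 list calls, so the count of calls does not set the real grouping apart. With the block, further calls ended without the pair numbered 1 for lysosome and ribosome biogenesis, without the pair numbered 2 for DNA replication, oxidative phosphorylation and histones, and without the pair numbered 3 for DNA replication, which turned to lower, and oxidative phosphorylation. Further lists passed as lower in HPC, namely lineage regulators and YAP/TAZ response after the length and GC correction, interferon response without the pair numbered 1, YAP/TAZ response without the pair numbered 2, and the dedifferentiated state and ATF4 response without the pair numbered 3. Of the genes named from the blocked fit, Adcy5, Tfap2a, Itgav, Slc16a3, Hk2, H2-K1, Hmox1, H3f3b, H1f0, Postn and Pdgfra did not pass without the pair numbered 3.

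**Figure D3:**
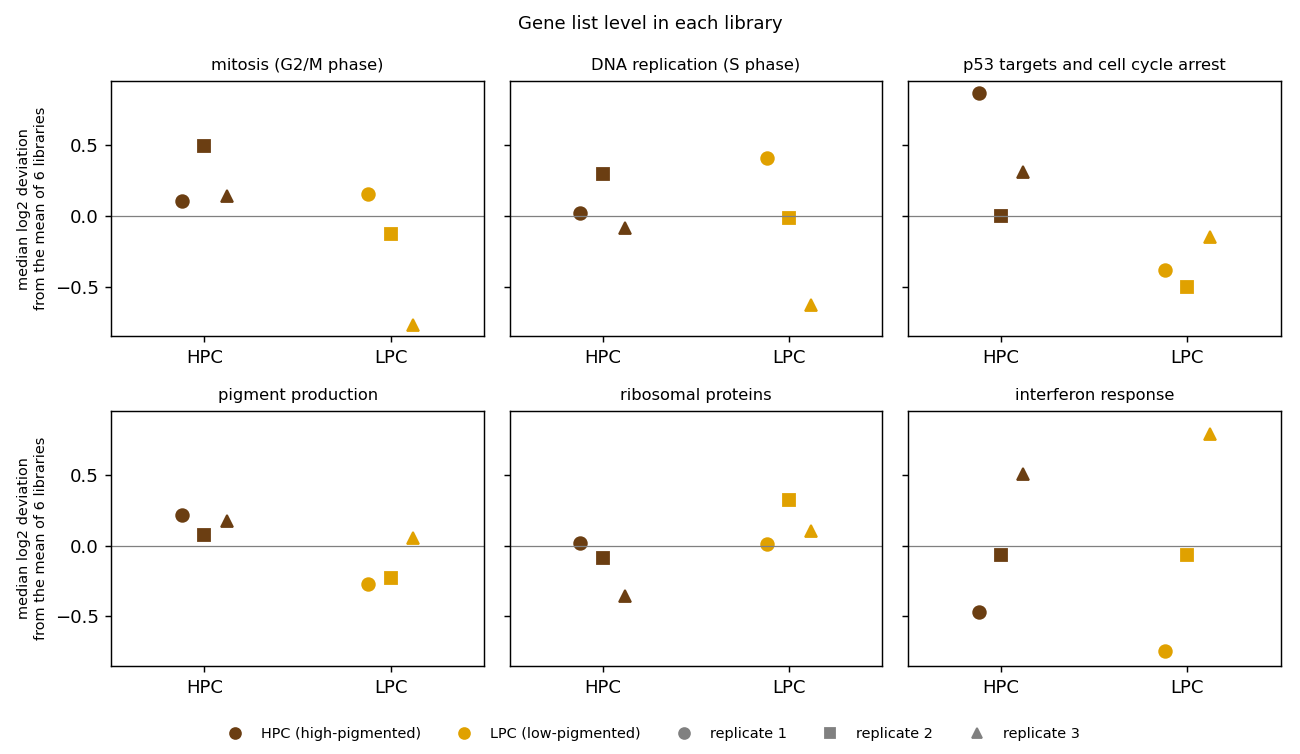
Median log2 deviation of 6 gene lists from the mean of the 6 libraries, by library; colour gives the group and symbol the replicate number. The p53 list lay higher in each HPC library than in any LPC library, whereas the interferon list lay lowest in both libraries numbered 1 and highest in both numbered 3.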

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

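The alternatives to the blocked fit were chosen after seeing the data; all others were planned. RLE, upper-quartile and library-size scaling, limma-voom and the stricter filter gave 4, 6, 5, 5 and 5 changed genes, all lower in HPC, with Myc lost under RLE (edgeR adjusted p = 0.0505). DESeq2 called 224 genes (122 higher, 102 lower, 105 at least 2-fold), edgeR with no filter 28 (12, 16 and 25) and edgeR with the replicate block 301 (170, 131 and 129). Leaving out single libraries gave 0 to 43 changed genes, 0 to 27 higher, 0 to 17 lower and 0 to 39 changed at least 2-fold; fewer libraries were tested there, and for the other shifts the cause was not tested. The 301 blocked calls became 500 with DESeq2, 616 with no filter, 298 with limma-voom, 312 with RLE and 307 with the length and GC correction, which kept 258 of them and lost Myo5a, Zmat3, Hk2 and Itgav among the named genes. Leaving out a pair, which left 1 residual degree of freedom, gave 0 to 2947, with 1020 genes at an unadjusted p under 0.05 in the fit with 0. All 301 had the same sign in each of these, except 1 without the pair numbered 3. These genes were chosen from the same libraries, so a shared sign was largely fixed in advance and is no support. Gene list calls fell from 10 to 0 with an estimated correlation (0 lists at an unadjusted p under 0.05) and to 0 with fry (2 lists at an unadjusted p under 0.05), and from 11 to 0 with the block and an estimated correlation; the other settings gave 8 to 13. Of 751 values of named genes under alternatives, 638 kept sign and side of the threshold, 85 newly passed, 21 no longer passed and 7 reversed, all 7 without a single library. Only 5 genes passed in the main fit, so most of the 638 are genes that passed in neither fit. All 5 calls were lost without HPC replicate 1, 2 or 3 or LPC replicate 2. Over the fits without a single library the log2 fold change ran from -0.27 to 0.047 for Mlana, -0.040 to 0.17 for Mitf, -0.098 to 0.020 for Sox10, -0.57 to 0.32 for Axl and -0.013 to 1.87 for Cited1. The block let 41 of the named genes pass and ended no call of a gene or list. Many of these 41 were named because they passed with the block, so that count is no support for it. Dividing the 6 libraries in all 10 possible ways, 1 division, the real one, gave 5 or more changed genes or 5 or more changed at least 2-fold (highest other 0), and 6 gave as many lists as the real 10 (highest other 12). Swapping labels within pairs, 1 of 4 arrangements, the real one, gave 301 or more genes (highest other 0) and 3 gave as many lists as the real 11 (highest other 12). So few divisions cannot give a share under 0.05. For the lists, other divisions and swaps called as many or more, so the number called does not set the real grouping apart. Genes of a few CPM, such as Ngfr and Ptprf, rest on few reads per library: the SE of the log2 fold change was 0.98 for Ngfr against 0.12 for Dct.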

Other observations

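Of the tests in this part, that of LPC replicate 1 holding HPC cells, that of the pluripotency genes and that of chromosome medians were chosen after the results were seen. The SEs in this part are bootstrap SEs, from resampling the genes of a set as if they were independent. They do not measure the spread between libraries, so what is read from them holds for these 6 libraries only.

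Part of the variation between libraries followed the replicate number rather than pigmentation. The first principal component, with 41.2% of the variance, set LPC replicate 1 (-37.7) against HPC replicate 3 (27.5) and LPC replicate 3 (26.9). HPC replicate 1 (-8.01) lay nearer to HPC replicate 2 (-3.57) and LPC replicate 2 (-5.11) than to LPC replicate 1. The second component, with 31.3%, separated HPC from LPC. Interferon response genes had list medians of -0.47, -0.064 and 0.51 in HPC replicates 1, 2 and 3 and of -0.74, -0.069 and 0.79 in LPC replicates 1, 2 and 3, as log2 deviations from the mean of the 6 libraries. The hypoxia and glycolysis list stood at -0.21, 0.063 and 0.19 in HPC and at -0.48, 0.15 and 0.26 in LPC.

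The pairs did not agree on growth-related lists. The gap in the mitosis median between the mean of the pairs numbered 2 and 3 and the pair numbered 1 was 0.83, and 0.85 (bootstrap SE 0.038) after each library's trend with transcript length and GC content was removed, which argues against that trend as its cause. HPC cells in LPC replicate 1 would have reduced the pigment difference as well, but the pigment production median was 0.34 higher in that pair than in the others (SE 0.14), which argues against them as the whole cause. A smaller share of such cells stays open. Tyr (1.80 against 3.78 and 2.06), Met (1.59 against 3.17 and 1.71), Zscan10 (-2.37 against -3.29 and -4.12) and Sall4 (-1.03 against -1.99 and -2.32) differed least in the pair numbered 1. Trpm1 (2.71 against 2.64 and 1.52), Tinagl1, Fam212b, Tbc1d2, Hmcn2, Cited1 and Ccng1 differed most in that pair. Both sets were picked from the named genes, so they decide nothing. Of the 301 genes called with the block, 113 differed least in the pair numbered 1, 47 in the pair numbered 2 and 141 in the pair numbered 3. The gap for ribosomal protein genes shrank from -0.42 to -0.16 (SE 0.029) under the correction, so a length or GC effect may account for part of it and stays open, as do differences in culture or sorting between replicate numbers, which no label records.

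For Tyr, a gain of chromosome copies around the gene was weighed with 26 tested genes within 5 Mb. Their median log2 fold change was -0.11 (SE 0.071) against 2.30 for Tyr, and no chromosome median exceeded 0.072 in size with the block. This argues against a gain of that size across the whole stretch or a large chromosomal difference. A median of 26 genes cannot detect a gain that covers only Tyr and a few neighbours. The 3 other scalings gave Tyr 2.27 to 2.30, but moved all genes too little to decide by themselves. A scaling factor moves all genes of a library alike, so it cannot change the gap between Tyr and the typical gene. The median log2 fold change over all tested genes was -0.0091. Under the 3 other scalings that median ran from -0.039 to -0.0049. These medians do not bear on Tyr, so they are no test of scaling as its cause. Grm5, 1 of the 26 neighbours, had a log2 fold change of 2.01 without passing (edgeR adjusted p = 0.32). A smaller gain around Tyr was not tested and stays open. Pigmentation itself, by which the cells were sorted, stays open and untested.

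The higher list of p53 targets and cell cycle arrest was weighed against transcript length and GC content. Its median log2 fold change with the block was 0.74 before and 0.67 (SE 0.23) after the trend was removed, which argues against the trend as its whole cause. A difference in damage or handling of the sorted populations and one tied to pigmentation both remain open and were not tested.

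Zscan10 and Sall4, both genes of embryonic stem cells, were lower in HPC, and the hypothesis that pluripotency genes as a set are lower was tested on 25 genes, of which 8 were expressed enough to test. Their median log2 fold change was -0.23 (SE 0.44), within its error of 0, and Lin28b stood at 1.23, so the set gave no answer either way.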
